A study of Oryza sativa with 39 samples.

How the data were processed

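The series measured total RNA of leaves of the rice variety Koshihikari, grown in a paddy field without special treatment, at 26, 47 and 61 days after transplanting. Each day gave 13 samples, at 2-h steps from 08:00 to 08:00 of the next day. The RNA was amplified and labelled with the Low Input Quick Amp kit, with Cy3 or Cy5, per the labels' protocols. Each of 20 arrays on 6 slides carried 2 samples of different dye. The dye alternated along the time course, and the alternation on day 47 ran opposite to that on days 26 and 61. Per the file headers, the intensity values were read with Agilent Feature Extraction 10.5.1.1, in which the processed signal is background-subtracted, detrended and dye-normalized within the array. The mean signal and the median background of each spot are intensity values with no normalization, per the file headers. The submitters' processing notes also name affy, with no step given, and no value from it was used. The well-above-background, saturation and outlier flags are 0 or 1 as deposited. The last array held 1 channel that belongs to no sample of this series, so 7 columns were not used.

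Each array had 156732 spots, of which 4854 were controls and 151878 were probes of 60 bases with 148841 different sequences. The files list every probe under its own ID, with no gene, description or position. None of the 151878 probe IDs matched a locus, symbol or accession in the table of rice genes given (assembly ASM3414082v1), so genes could not be named. The 21 gene lists with 245 genes that were fixed before the data were examined could therefore not be applied, and their shifts were not tested. In place of genes, sequences that share at least 25 consecutive bases on the same strand were joined into 103083 targets, of which 71866 hold 1 sequence. A target is not a gene, since 1 transcript can have several probes that do not overlap. The 25 bases were chosen after the files were seen.

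Log2 processed signals of the probes were quantile-normalized over the 39 channels, and spots of the same sequence were averaged. A total of 248 sequences with an outlier flag in any sample were left out, as were sequences well above background in fewer than 3 of the 39 samples. This left 103402 sequences and 68973 targets, each read through its brightest sequence. The processed signal rose over the days: its median log2 value per channel before quantile normalization was 4.75 ± 0.16 on day 26, 5.57 ± 0.24 on day 47 and 6.05 ± 0.27 on day 61 (mean ± SD over 13 samples). The median of the mean signal, which has no normalization, did not rise at each step. In Cy3 channels it ran from 85.46 to 106.3 on day 26, 69.88 to 98.8 on day 47 and 105.8 to 136.2 on day 61. In Cy5 channels it ran from 141.7 to 155.8, 156.3 to 194.8 and 207.4 to 303. Duplicate spots of 3014 sequences differed by a median of 0.0691 to 0.0928 on the log2 scale, depending on the sample. Overlapping probes of the same strand had a median correlation of 0.97 across samples (45795 pairs of probes, which are not independent replicates), and 94.5% of the pairs had a correlation above 0.5. The number of arrays limits the precision.

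Tests used limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with Benjamini-Hochberg adjusted p under 0.05. The model held day, dye and cosine and sine terms with periods of 24 h and 12 h, with the array as a random block whose correlation was estimated from 5000 targets (0.51). A daily rhythm was called from the F test of the 4 harmonic terms, with peak time and peak-to-trough difference read from the fitted curve. Midday against midnight was a contrast in a fit with clock time as a factor of 12 levels, day contrasts came from the day terms, and the rhythm between days from the interaction of day and harmonics. With 1 sample per day and time point, p-values measure only the spread of these samples around the fitted course. Samples of a day came in sequence from a single day and may not be independent. Same-numbered samples were taken at the same clock time on each day: the lowest correlation over targets of their deviations from the day means was 0.28 and the median was 0.47, so the time point pairs the samples. Peak times per day were compared over targets with a 24-h range of at least 0.5 on every day. A jackknife over the 13 time points gave the SE. For this comparison peak time and range came from the 24-h terms alone, so a change in the shape of the course can also move them. The comparison was chosen after seeing the data. The same holds for that of the 2 samples of 08:00 on the slide shared by days 26 and 47.

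The probes named are those that the rule fixed in advance ranks first, without its condition that a gene can be named. They are the largest fitted rhythm, split by a peak from 06:00 to 18:00 or outside it, the largest changes at midday with separated values, the largest day changes with the same sign at 13 time points, and the smallest interaction p. At most 2 probes that rose and 2 that fell were printed per comparison. A probe not well above background in any sample of a group has only a bound there. The fold is then given as "at least", from the mean of the brighter group against the mean of, per sample, the higher of its own value and the lowest signal among tested probes well above background. This lowest signal is a convention and not the detection limit of the probe itself. Dim values can be higher: eAry1_31538 had 4.991 in 1 sample of day 26 without being well above background.

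Alternatives were normexp background correction with an offset of 50, scaling to the 75th percentile, normexp followed by loess and Aquantile normalization on the 19 arrays with both channels in the series, and a filter of 13 samples or none. Further ones were the mean of a target's probes, an intensity trend in eBayes, fits without dye or array, slide as a fixed or random block, the time point as a block, 24-h terms only, days left out and the second 08:00 sample left out. The fits and calls were tested on simulated data of 68973 targets with 200 changed ones and the spread measured around the rhythm fit. Normalization, the filter and the choice of the brightest sequence were not part of this test. Noise was independent between targets and held no slide effect. With few changed targets the Benjamini-Hochberg cutoff is stricter than in the data, so the recovered shares do not carry over to the counts reported here. Of targets simulated with a change of 2 on the log2 scale, 84.8% were recovered for the daily rhythm, 87.9% for midday against midnight, 90.9% for day 61 against day 26 and 47% for a rhythm on day 47 alone. At a change of 1, these shares were 47.8%, 53.7%, 64.2% and 5.97%. Figures were drawn with matplotlib 3.10.9.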

Results

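Leaves of field-grown rice of the variety Koshihikari were sampled every 2 h from 08:00 to 08:00 of the next day, at 26, 47 and 61 days after transplanting. Each of the 3 days gave 13 samples, so the series held 39 samples in all. The labels name no replicate of a time point: clock times are repeated only over the 3 days and at the 2 samples taken at 08:00 of each day. Total RNA was measured on 2-colour microarrays with 151878 probes of 60 bases, on which 2 different samples shared an array, one labelled with Cy3 and the other with Cy5. A mean of 55.3% ± 2.9 of the probes were well above background on day 26 (SD, n = 13 samples). The same share was 60.4% ± 1.8 on day 47 (SD, n = 13) and 63.2% ± 1.4 on day 61 (SD, n = 13), and no probe spot was saturated. The number of arrays limits the precision of every value given here. The files pair no probe with a gene, so the results are given for targets, that is, groups of probes that overlap in sequence on the same strand, each read through its brightest probe. Of 103083 targets, 68973 passed the filter on dim probes and were tested.

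The first question, set by the 2-h sampling over a day, was which transcripts followed a daily course. Targets peaking from 05:00 to 11:00 and from 11:00 to 17:00 made up the largest groups. Among the 29476 targets with a daily rhythm of at least 2-fold between fitted peak and trough, 7952 (27%) peaked from 05:00 to 11:00 and 9058 (30.7%) from 11:00 to 17:00. A further 6200 (21%) peaked from 17:00 to 23:00 and 6266 (21.3%) from 23:00 to 05:00. By single sampling times, 3796 targets peaked nearest to 06:00 and 3432 nearest to 14:00, against 1528 nearest to 00:00. The median peak-to-trough difference on the log2 scale was 1.71 in the group of 05:00 to 11:00, 1.80 in that of 11:00 to 17:00, 1.70 in that of 17:00 to 23:00 and 1.73 in that of 23:00 to 05:00. The set of 29476 fell to 18480 targets with normexp background correction and to 18402 with normexp, loess and Aquantile together, and the peak groups were not counted in those.

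**Figure D1:**
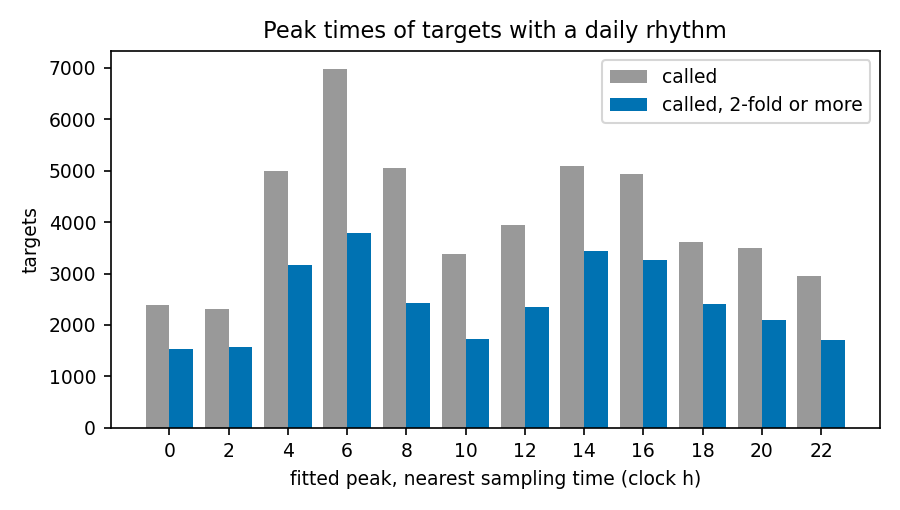
Number of targets with a daily rhythm by fitted peak time, rounded to the nearest sampling time, for all called targets (grey) and those with at least a 2-fold difference between peak and trough (blue). Counts of the 2-fold targets were highest at 06:00 (3796) and 14:00 (3432) and lowest at 00:00 (1528).

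The widest daily courses spanned most of the range of the arrays. Probe eAry2_32949 (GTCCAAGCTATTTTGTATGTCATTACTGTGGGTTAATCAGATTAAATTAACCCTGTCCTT) had a log2 signal of 12.68 ± 0.23 at 08:00 (SD, n = 6) and 2.85 ± 1.63 at 20:00 (SD, n = 3), where it was not well above background in any sample, and was at least 639-fold higher at 08:00. Probe eAry1_33300 (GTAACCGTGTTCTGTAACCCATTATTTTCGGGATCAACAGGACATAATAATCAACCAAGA) had a log2 signal of 10.98 ± 1.12 at 16:00 (SD, n = 3) and was at least 312-fold lower at 06:00, where it was not well above background in any of the 3 samples. Among targets with a peak in the other part of the day, probe eAry1_30296 (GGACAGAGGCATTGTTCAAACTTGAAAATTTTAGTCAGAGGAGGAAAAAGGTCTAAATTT) had the widest fitted difference, 10.73 on the log2 scale, with 13.59 ± 0.36 at 06:00 (SD, n = 3) and 3.66 ± 2.63 at 18:00 (SD, n = 3, well above background in 1 sample). Probe eAry2_23942 (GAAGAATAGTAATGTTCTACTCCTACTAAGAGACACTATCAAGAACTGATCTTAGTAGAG) had a fitted difference of 10.34, with 12.94 ± 0.41 at 06:00 and 3.23 ± 2.67 at 18:00 (SD, n = 3 each, well above background in 1 sample at 18:00). The adjusted p of limma's moderated F test was 3.1e-15, 1.4e-11, 9.3e-14 and 1.1e-13 for these 4 probes in turn. The differences of all 4 rest in part on values not well above background, and both bounds hold for the processed signal only. Probes eAry1_30296 and eAry2_23942 ran close to each other over the time course, and whether they read the same transcript was not tested. With normexp background correction, whose offset raises dim values, the fitted differences on the log2 scale were 7.36 for eAry2_32949 (10.05 without it), 6.10 for eAry1_33300 (9.45 without it), 8.31 for eAry1_30296 and 7.51 for eAry2_23942.

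In total, 49136 of 68973 targets (71.2%) had a daily rhythm by limma's moderated F test of the 24-h and 12-h terms, and 11204 (16.2%) had one of at least 4-fold. Because days served as the repeats, each day was also compared with the course fitted to the others. Targets were sorted into the 4 peak groups from 2 days, and their mean course was then read on the day left out. On day 61, targets that peaked from 05:00 to 11:00 on the other days had their highest mean at 06:00 (0.78 above the mean of the day on the log2 scale, 7423 targets), and those of 17:00 to 23:00 had theirs at 20:00 (0.86, 5333 targets). Peak times on the day left out lay within 3 h of those on the other days for 64.4% of targets on day 26, 84.7% on day 47 and 86.9% on day 61, where unrelated peak times would give 25%.

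**Figure D2:**
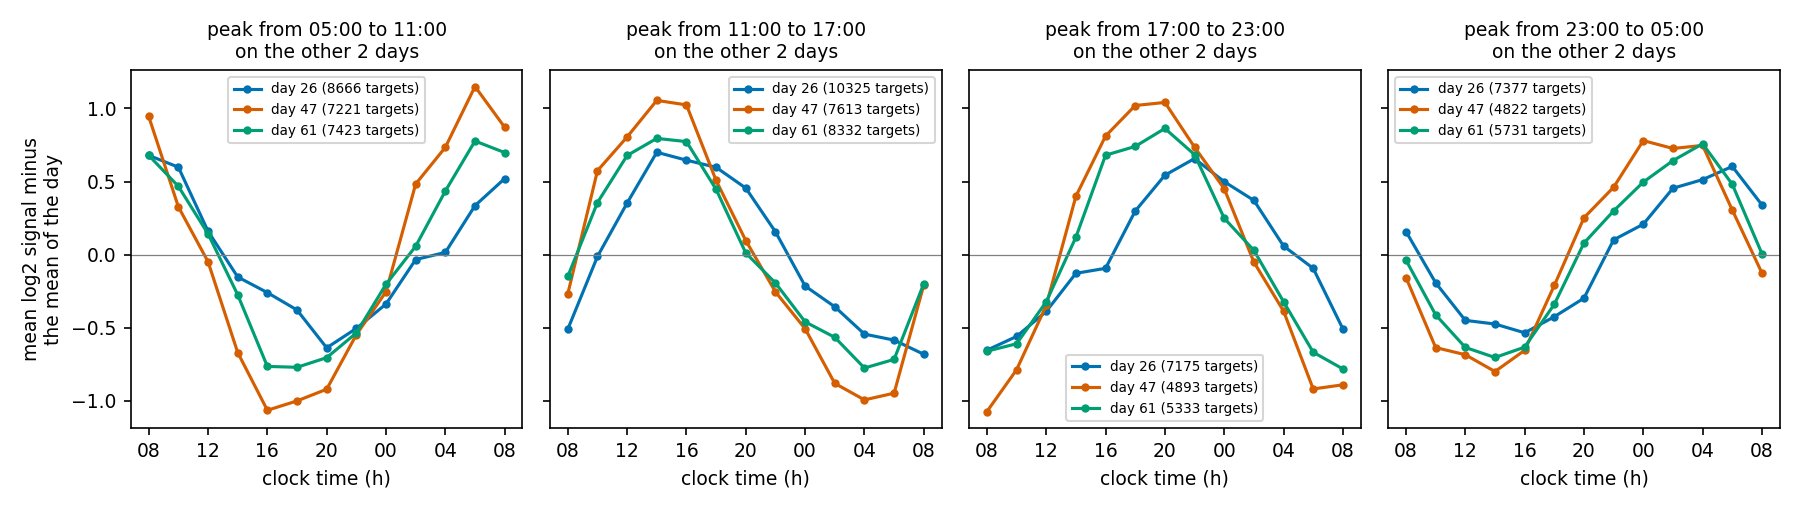
Mean log2 signal minus the mean of the day (vertical axis) against clock time (horizontal axis) on each day, for targets assigned to a peak group from the other 2 days only, with at least a 2-fold fitted difference there. Points are means over the number of targets given in each panel. The highest point of the group of 17:00 to 23:00 lay at 20:00 on days 47 and 61 and at 22:00 on day 26. That of 05:00 to 11:00 lay at 06:00 on days 47 and 61 and at 08:00 on day 26. That of 11:00 to 17:00 lay at 14:00 on each day. For the group of 23:00 to 05:00 it lay at 06:00 on day 26, 00:00 on day 47 and 04:00 on day 61.

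Midday (10:00, 12:00 and 14:00) was compared with midnight (22:00, 00:00 and 02:00) as a contrast that assumes no wave shape, with 9 samples on each side. Probe eAry2_32593 (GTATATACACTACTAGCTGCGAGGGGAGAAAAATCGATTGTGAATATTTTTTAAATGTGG) was higher at midday by 7.51 ± 0.56 (SE) on the log2 scale, with a signal of 10.11 ± 0.42 at midday and 2.64 ± 1.01 at midnight (SD, n = 9 each). It was well above background in only 1 midnight sample, so the size rests on values at background level, and it was 4.68 with normexp background correction. Probe 44kb3_25894 (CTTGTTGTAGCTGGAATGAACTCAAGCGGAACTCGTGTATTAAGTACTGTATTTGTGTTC) was higher at midday by 7.35 ± 0.76 (SE), with 13.44 ± 0.53 against 5.95 ± 2.77 (SD, n = 9 each, well above background in 7 midnight samples). Probe 44kb3_41367 (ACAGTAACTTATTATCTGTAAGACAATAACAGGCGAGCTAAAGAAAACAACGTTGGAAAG) fell by 7.42 at midday relative to midnight (SE 0.44), from 13.77 ± 0.32 to 6.30 ± 1.23 (SD, n = 9 each), and probe eAry2_28990 (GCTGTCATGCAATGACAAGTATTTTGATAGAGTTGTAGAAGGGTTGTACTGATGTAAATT) fell by 7.37 (SE 0.43), from 14.33 ± 0.30 to 6.97 ± 1.15 (SD, n = 9 each). Their adjusted p values from limma were 2.3e-10, 2.8e-08, 9e-12 and 7.9e-12. Probes 44kb3_41367 and eAry2_28990 ran close to each other over the time course, and whether they read the same transcript was not tested. Of all targets tested, 31208 differed (limma, adjusted p under 0.05), 15157 higher and 16051 lower at midday, of which 5260 and 5706 by at least 2-fold (10966 in all, against 5825 with normexp alone and 5801 with normexp, loess and Aquantile together). The 9 midday values lay wholly above the 9 midnight values for 2110 targets and wholly below for 2115. If these samples were independent, chance would separate 0.0041% of targets, but each side holds neighbouring time points of the same 3 days. Leaving out day 47 gave 17757 targets, and leaving out day 61 gave 20517.

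The 3 days were then compared with each other at matched clock times. Probe eAry1_33616 (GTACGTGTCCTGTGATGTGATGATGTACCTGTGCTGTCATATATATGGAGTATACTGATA) was higher on day 61 than on day 26 by 8.02 ± 0.53 (SE) on the log2 scale, with 15.45 ± 0.73 against 7.40 ± 0.67 (SD, n = 13 each). Probe PPNTpc_00175 (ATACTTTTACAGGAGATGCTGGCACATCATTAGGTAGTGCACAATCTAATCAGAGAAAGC) was higher by 6.85 ± 0.70 (SE), with 11.01 ± 0.76 against 4.00 ± 2.03 (SD, n = 13 each, well above background in 7 samples of day 26). Probe eAry1_24410 (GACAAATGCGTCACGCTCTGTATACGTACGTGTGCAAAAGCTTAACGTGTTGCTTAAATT) fell by 9.43 (SE 0.99), from 14.99 ± 0.63 on day 26 to 5.40 ± 3.96 on day 61 (SD, n = 13 each, well above background in 8 samples of day 61). Probe 44kb3_12124 (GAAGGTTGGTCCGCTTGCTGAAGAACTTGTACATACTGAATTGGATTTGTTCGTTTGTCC) fell by 8.59 (SE 0.57), from 12.51 ± 0.67 to 3.79 ± 1.64 (SD, n = 13 each, well above background in 8 samples of day 61). The adjusted p from limma was 3.1e-14, 4.7e-10, 8.6e-10 and 3.1e-14 for these 4 probes. The same direction at all 13 time points was a condition for naming them. The fall of eAry1_24410 varied over the day: at 10:00 it had 14.0 on day 61 against 15.5 on day 26. Its fitted daily range was 11.84 on day 61 and 1.48 on day 26. With normexp background correction the change of PPNTpc_00175 was 4.96, that of eAry1_24410 -7.75 and that of 44kb3_12124 -6.55, all 3 probes that were not well above background in some samples of their dimmer day.

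Between day 61 and day 26, 41944 of 68973 targets differed (60.8%, limma), 22363 (53.3%) higher and 19581 lower on day 61. The side with more calls turned with 75th percentile scaling, where 44.2% of the calls were higher, and with no filter on dim probes, where 46.2% were. At least a 2-fold change was found for 8700 higher and 7021 lower targets, 15721 in all, against 6605 with normexp alone, 6551 with normexp, loess and Aquantile together and 9118 with slide as a fixed block. The direction was the same at all 13 time points for 11990 higher and 9998 lower targets. If the time points were independent, chance would give 0.024% of targets. The samples of a day came in sequence, however, and may share an offset of that day or its slides. No slide held samples of both days. The count was 12773 with slide as a fixed block, of which 11850 were also called without the block.

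Between day 47 and day 26, probe eAry2_18353 (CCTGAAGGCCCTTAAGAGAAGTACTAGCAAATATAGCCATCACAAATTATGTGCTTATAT) had a log2 signal of 8.32 ± 0.84 on day 47 and was not well above background in any of the 13 samples of day 26, which makes it at least 37-fold higher on day 47 (limma, adjusted p = 4.3e-13). Probe eAry1_31538 (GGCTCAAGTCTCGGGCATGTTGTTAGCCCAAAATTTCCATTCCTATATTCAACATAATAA) was at least 34-fold higher on day 47 by the same bound, with 8.43 ± 1.06 (SD, n = 13, adjusted p = 5.8e-12 from limma). In the other direction, probe eAry1_24940 (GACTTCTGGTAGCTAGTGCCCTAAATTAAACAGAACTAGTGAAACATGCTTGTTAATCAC) had 7.17 ± 0.50 on day 26 and was at least 21.3-fold lower on day 47, and probe eAry2_16215 (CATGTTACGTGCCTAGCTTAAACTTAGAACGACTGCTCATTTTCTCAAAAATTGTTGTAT) had 6.92 ± 0.51 on day 26 and was at least 17.2-fold lower (SD, n = 13 each). Both were not well above background in any sample of day 47. They ran close to each other on day 26, and whether they read the same transcript was not tested. These bounds hold only for the processed signal, with the lowest signal well above background as the floor. With normexp background correction, whose offset raises dim values, the fitted changes of the 4 probes were 3.05, 2.91, -2.28 and -2.00 on the log2 scale. A total of 31293 targets differed by limma, 16363 higher and 14930 lower on day 47. Of the calls 52.3% were higher, against 47.1% with 75th percentile scaling, 46.8% with no filter on dim probes and 48.5% with slide as a fixed block, so the side with more calls is not settled. The slide that held both days had 7 samples of day 26, from 20:00 to 08:00, and only 1 of day 47, at 08:00. Within it 737 targets passed the test, which assumes that the lone sample varies like the others. Of the 29991 targets called without that slide, 70.6% had the same direction between its 2 samples of 08:00, which shared an array with opposite dyes. A fit with slide as a fixed block called 13365 targets, of which 10096 were also called without the block.

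Between day 61 and day 47, probe eAry1_33709 (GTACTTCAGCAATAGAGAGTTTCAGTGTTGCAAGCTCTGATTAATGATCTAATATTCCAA) was higher on day 61 by 5.95 ± 0.32 (SE) on the log2 scale, with 8.17 ± 0.65 against 2.14 ± 1.02 (SD, n = 13 each). It was well above background in only 1 sample of day 47, so the size rests on values at background level, and it was 2.92 with normexp background correction. Probe eAry1_21950 (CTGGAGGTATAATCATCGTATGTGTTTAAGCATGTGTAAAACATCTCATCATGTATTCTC) was higher by 5.78 ± 0.59 (SE), with 9.35 ± 1.12 against 3.70 ± 1.46 (SD, n = 13 each, well above background in 5 samples of day 47), and by 3.45 with normexp. Probe eAry1_24410, the one with the widest fall from day 26 to day 61, fell by 7.01 from day 47 to day 61 (SE 0.99), and by 5.42 with normexp. Probe eAry1_14756 (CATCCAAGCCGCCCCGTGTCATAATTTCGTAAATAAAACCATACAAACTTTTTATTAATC) fell by 6.42 (SE 0.38), from 13.15 ± 0.64 to 6.70 ± 1.25 (SD, n = 13 each). In all, 25445 targets differed by limma, 13429 (52.8%) higher and 12016 lower on day 61; with 75th percentile scaling in place of quantile normalization, 42.6% of the calls were higher. One slide held 4 samples of each day, those of day 47 from 02:00 to 08:00 and those of day 61 from 08:00 to 14:00. Of the 14466 targets called without this slide, 94% had the same direction within it after the fitted daily course was removed, with a median change of 0.59 on the log2 scale within it and 0.66 without it. At 08:00, the only clock time that both days had on this slide, the direction was the same for 91%. The fit with slide as a fixed block called 13558, of which 11555 were also called without the block. Each stage was sampled on 1 day, so stage and the conditions of that day cannot be told apart.

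**Figure D3:**
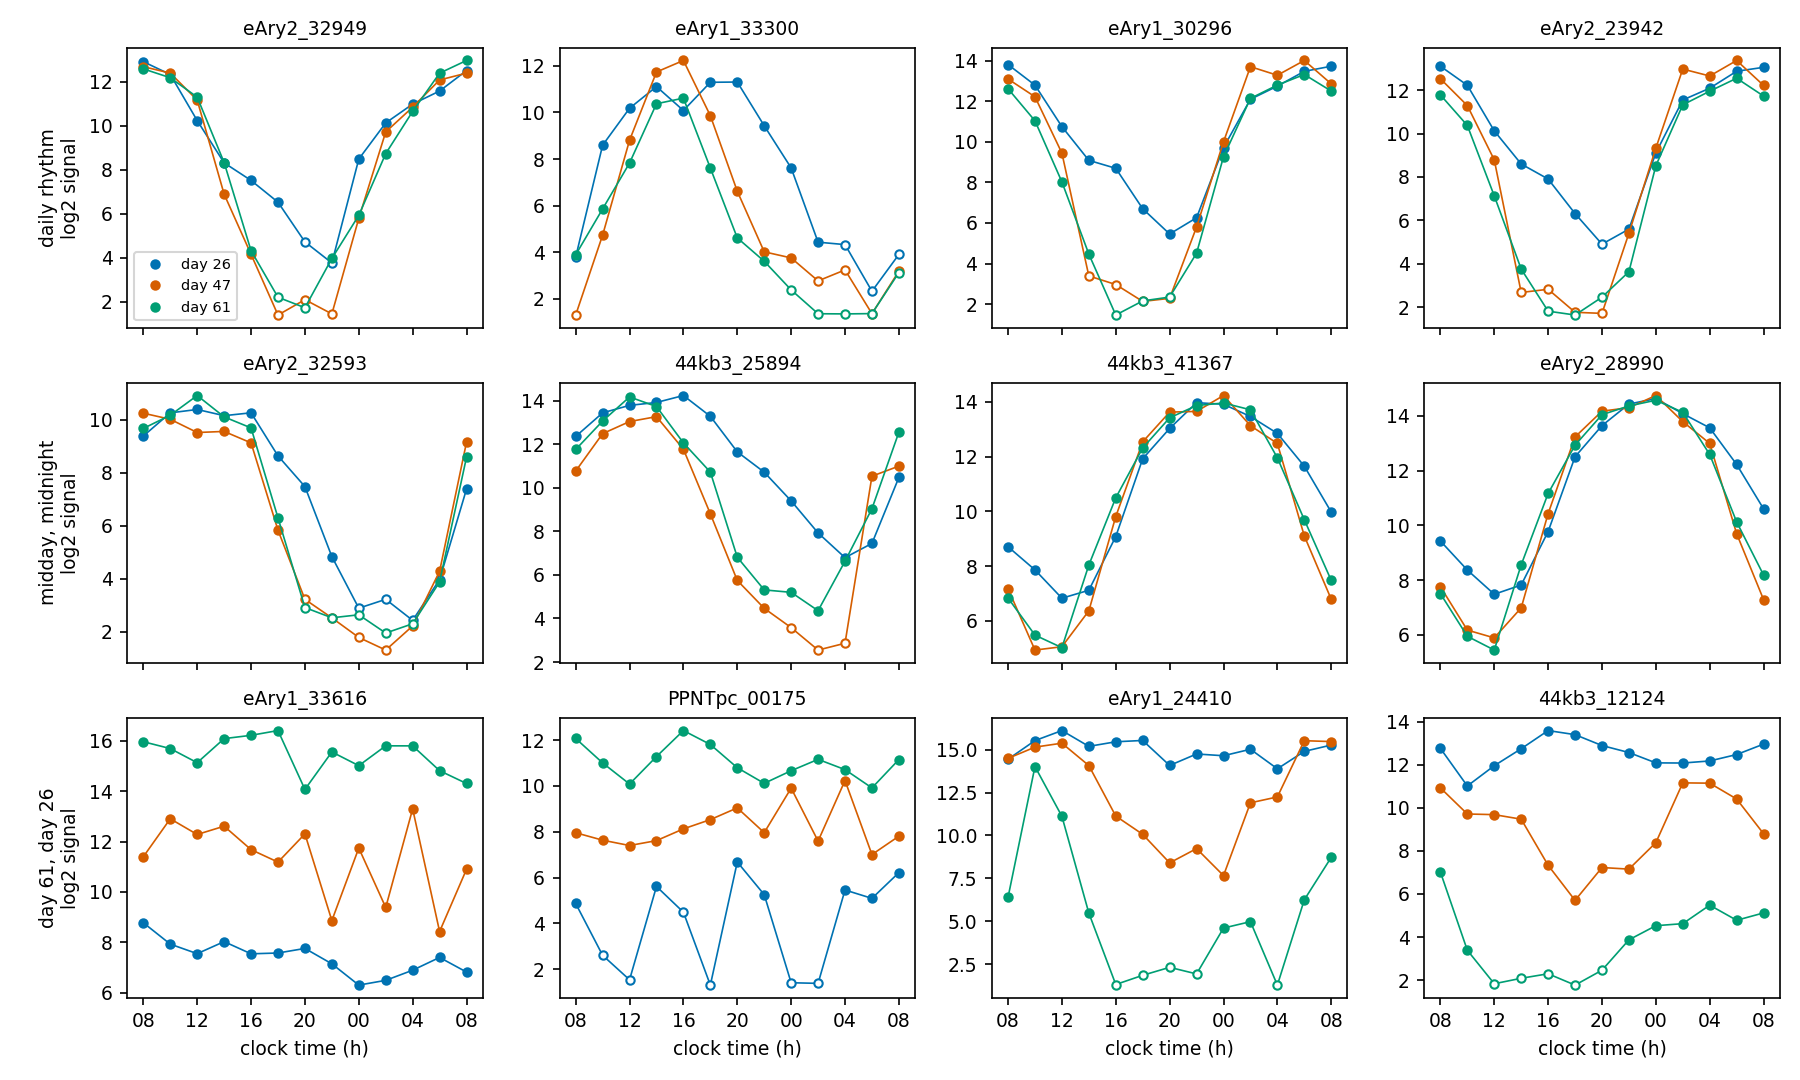
Log2 signal (vertical axis) against clock time (horizontal axis) of the probes named for the daily rhythm (top row), midday against midnight (middle row) and day 61 against day 26 (bottom row), 1 point per sample, coloured by day. Open points are samples in which the probe was not well above background. In the bottom row days 26 and 61 lie apart at all 13 time points, which was a condition for naming these probes.

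The same course on 3 days allowed a test of whether the rhythm itself differed between days. Probe 44kb3_32908 (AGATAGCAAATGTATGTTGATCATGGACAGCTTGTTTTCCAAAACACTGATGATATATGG) had a fitted daily range of 1.83 on day 26, 5.09 on day 47 and 4.92 on day 61 on the log2 scale. For probe 44kb3_1168 (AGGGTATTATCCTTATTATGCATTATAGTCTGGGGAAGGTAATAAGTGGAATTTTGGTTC) the ranges were 2.58, 6.95 and 7.08 in the same order of days. Probe eAry2_13887 (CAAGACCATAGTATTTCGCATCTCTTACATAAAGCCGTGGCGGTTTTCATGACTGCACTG) had ranges of 1.42, 4.68 and 4.67, and probe 44kb3_35373 (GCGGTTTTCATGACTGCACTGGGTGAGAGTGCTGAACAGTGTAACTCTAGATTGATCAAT), which shares 21 consecutive bases with it, had 1.40, 4.40 and 4.42. The adjusted p of limma's F test of the interaction was 1.2e-13, 2e-12, 1.9e-12 and 2.5e-12. A total of 24960 targets (36.2%) differed in rhythm between days, and the fitted range was widest on day 47 for 14889 of them, on day 26 for 6375 and on day 61 for 3696. With slide as a fixed block, 11698 targets were called, 10891 of them shared with the fit without it.

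Over the 33694 rhythmic targets with a 24-h range of at least 0.5 on the log2 scale on every day, the median range was 1.38 ± 0.06 on day 26, 1.78 ± 0.05 on day 47 and 1.39 ± 0.04 on day 61 (jackknife SE over the 13 time points). With slide as a fixed block these were 1.3 ± 0.12, 1.66 ± 0.17 and 1.41 ± 0.10. The median log2 ratio of the ranges was 0.35 ± 0.07 for day 47 over day 26 and -0.33 ± 0.04 for day 61 over day 47, and with the block it was 0.34 ± 0.21 and -0.22 ± 0.16, less than 2 jackknife SE from 0. Peak times of the 24-h terms on day 47 minus those on day 26 had a median of -1.78 ± 0.24 h (jackknife SE), so the 24-h component came earlier on day 47. Day 61 minus day 26 had a median of -1.59 ± 0.23 h, and day 61 minus day 47 one of 0.19 ± 0.17 h. By peak group, the shift of day 47 against day 26 was -1.88 ± 0.29 h for 05:00 to 11:00, -1.70 ± 0.33 h for 11:00 to 17:00, -2.20 ± 0.31 h for 17:00 to 23:00 and -1.41 ± 0.27 h for 23:00 to 05:00. The same 4 shifts were -1.20 ± 0.58, -1.81 ± 1.02, -1.49 ± 0.61 and -1.52 ± 0.40 h with slide as a fixed block, so their order over the groups changed. With the block, the shifts over all these targets were -1.53 ± 0.55 h on day 47 and -1.24 ± 0.81 h on day 61, each against day 26 (jackknife SE).

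The samples taken at 08:00 a day apart show how far 2 samples of the same clock time differed. Over targets well above background in all samples, the SD of their log2 difference was 0.39 on day 26, 0.382 on day 47 and 0.342 on day 61. Samples 2 h apart had a median SD of 0.366, 0.449 and 0.423 on those days, and samples 12 h apart one of 0.954, 1.22 and 1.04. On day 47 none of the other 77 pairs of samples was closer than the 08:00 pair, on day 61 there were 2 such pairs and on day 26 there were 7. The 2 samples of 08:00 of a day had the same dye and lay on different slides. Samples 12 h apart also had the same dye. Samples 2 h apart always had opposite dyes, and 18 of these pairs shared an array. These SDs therefore mix time with dye, array and slide.

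**Figure D4:**
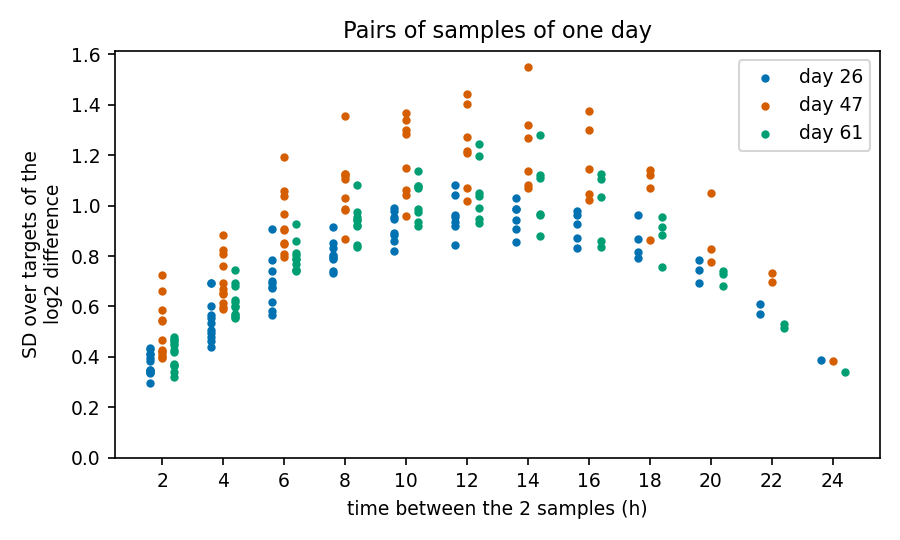
SD over targets of the log2 difference between 2 samples of one day (vertical axis) against the time between them (horizontal axis), 1 point per pair, coloured by day. The SD rose to a median of 0.954 to 1.22 at 12 h and was 0.342 to 0.39 at 24 h. Whether the 2 samples shared a dye, an array or a slide also varied with the time between them.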

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

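The tests of dye alone and of shared arrays or slides as the cause of the daily rhythm, the comparison of the spread of bright and dim targets, the sizes and SEs before and after the slide block, and that of the 2 samples of 08:00 on the slide shared by days 26 and 47 were chosen after the results were seen. The peak time shift was chosen after the rhythms had been fitted, and the remaining tests in this part were written beforehand. No test of single outlying samples was run.

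The rhythm differed between days for 24960 targets by the test of the interaction, and among the probes named it differed for 13. Of those with the widest rhythm, the adjusted p of limma's interaction test was 0.014 for eAry2_32949, 7e-04 for eAry1_33300, 0.0015 for eAry1_30296 and 0.0044 for eAry2_23942. Among the probes named for midday against midnight it was 0.0014 for 44kb3_25894, 1.5e-05 for 44kb3_41367 and 0.00011 for eAry2_28990. For probes named for day 61 against day 26 it was 0.0041 for eAry1_24410 and 0.002 for 44kb3_12124. The 4 probes chosen for the smallest p had 1.2e-13 for 44kb3_32908, 1.9e-12 for eAry2_13887, 2e-12 for 44kb3_1168 and 2.5e-12 for 44kb3_35373. In 100 splits that exchanged the days within time points, the real one included, only the real one (1 split) gave as many targets. The highest of the others gave 2819, which argues against a random assignment of samples to days. The splits break up the course of each day, so they cannot exclude chance differences between single days, arrays or slides. Slides held consecutive stretches of a day, so a slide effect could look like a daily course on that day alone. With slide as a fixed block 43.6% of the calls held, and for these 10891 slide as fitted is not the whole cause. Over the 14069 that ended, the median size of the day-specific terms along the direction fitted without the block went from 0.81 to 0.60 on the log2 scale while their median SE rose from 0.12 to 0.16. The share that held lay under the 50% set beforehand, but the loss comes in part from precision and leaves slide open for the calls that ended. The block also removes real differences between parts of a day.

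Peak times of the 24-h terms were earlier on days 47 and 61 than on day 26 over 33694 rhythmic targets. With slide as a fixed block the median shift of day 61 against day 26 was -1.24 h with a jackknife SE of 0.81 h, which lies below the -1 h set beforehand but not by enough to exclude slide. Stage, day length and the temperature of each day stay open as biological explanations, and none was tested, since each stage was sampled on 1 day.

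The differences between days and over the day were larger than those of random splits. Only the real grouping (1 of 100 in each case) reached its count. For the daily rhythm the real count was 49136 and the highest of the others 3; for midday against midnight 31208 and 16419; for day 47 against day 26 31293 and 7796; for day 61 against day 47 25445 and 12630; and for day 61 against day 26 41944 and 23109. A random assignment of the samples is thus argued against for each. The splits treat the samples of a day as independent, so they cannot exclude chance differences between single days, arrays or slides. Dye is argued against as the cause of the rhythm: targets called from the 20 Cy3 samples alone had peak times in the 19 Cy5 samples that differed by a median of 0.6 h, where about 6 h would be seen for unrelated times. Shared arrays or slides are argued against as its whole cause, since the days lay mostly on different slides and at least 64.4% of targets had a peak time on a day left out within 3 h of that on the other days, against 25% for unrelated times. Slide is argued against as the whole cause of the difference between day 61 and day 47 for the 14466 targets called without the slide that held both days. Of these, 94% had the same direction within it, though both days shared only 08:00 there, in 1 pair of opposite dyes. With slide as a fixed block 45.4% of the 25445 calls held (11555). Over the 13890 that ended, the median change went from 0.51 to 0.45 on the log2 scale and the median SE from 0.14 to 0.28. Those calls ended largely because the error widened, and slide stays open for them. For day 47 against day 26 slide stays open. Of the targets called without the slide that held both of these days, 70.6% had the same direction between its only 2 samples of 08:00. With slide as a fixed block 32.3% of the 31293 calls held (10096), but only 1 sample of day 47 links the days in that fit. Brighter channels on later days stay open for day 61 against day 26. In the brightest of 4 equal groups of targets 67% were called, against 46.1% in the dimmest, but the bound set beforehand on these shares decides nothing: the dimmest group had a median SD around the fitted course of 0.61, against 0.191, so it has less power. No slide held both of these days, and slides link them only through day 47, by 1 sample of it on the slide shared with day 26. With slide as a fixed block 28.3% of the 41944 calls held (11850). That fit rests on the same lone sample of day 47, so it cannot settle slide for the calls that held either. Over the 30094 that ended, the median change went from 0.71 to 0.52 on the log2 scale and the median SE from 0.16 to 0.43, so calls ended largely because the error widened, and slide stays open for them.

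Control spots of 3 kinds outside the comparisons also gave signal above the negative controls, of which at most 2.33% were well above background in any sample. A median of 100% of the E1A spike-in spots, 86.1% of the DCP spots and 4.23% of the ETG spots (0.385% to 8.46% by sample) were well above background. For the 720 ERCC spots the median was 1.67% (0.139% to 3.33%), against 1.17% for the negative controls.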

How the results depend on the processing

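The alternatives were listed before the data were examined, except every probe sequence on its own and the settings for the peak time shift. No named probe changed direction or lost its call under the alternatives run for it (364 values). Testing every probe sequence on its own, 103402 in place of 68973 targets, raised all counts: daily rhythm to 76603 (45084 of at least 2-fold), midday against midnight to 49492, day 47 against day 26 to 48306, day 61 against day 47 to 39641, day 61 against day 26 to 64506 and rhythm differing between days to 41400. With slide as a fixed block the counts were 13365, 13558 and 12773 for the day contrasts in that order and 11698 for the rhythm between days, and the peak time shifts moved to -1.53 h for day 47 and -1.24 h for day 61. Over the calls that ended, the median SE rose from 0.14 to 0.28, 0.14 to 0.28, 0.16 to 0.43 and 0.12 to 0.16 in that order, and the median size fell to 54.2%, 88.6%, 72.6% and 73.9% of its value (chosen after seeing the data), so both a wider error and a smaller size ended calls. Within the slide that held days 47 and 26, with 1 sample of day 47, 737 targets were called, which rests on fewer samples; for day 61 against day 26 no slide allowed this. Normexp alone gave 18480 rhythms of at least 2-fold, against 29476, and normexp, loess and Aquantile together on complete arrays gave 18402 (loess was not run without normexp), and the cause was not tested; calls of at least 2-fold between day 61 and day 26 likewise went from 15721 to 6605 and 6551. Of day 47 against day 26 they went from 8080 to 2477 and 2372, of day 61 against day 47 from 5098 to 1961 and 2013, and of midday against midnight from 10966 to 5825 and 5801. Leaving out each day in turn gave 39656 to 51842 rhythms (24549 to 33543 of at least 2-fold) and 17757 to 33276 targets differing between midday and midnight, the lowest without day 47 and 20517 without day 61; without day 47 dye follows clock time and was left out of that fit. With the time point as a block, which pairs samples of the same clock time, 28406, 22461 and 40077 targets were called in the 3 day contrasts, so the pairing changed no count by over 1.5 times. With 75th percentile scaling 42.6% of the calls between day 61 and day 47 were higher, against 52.8%, and the mean SD of the 08:00 pairs was 0.386 against 0.371. Higher calls between day 61 and day 26 went from 53.3% to 44.2% with that scaling and 46.2% with no filter, and those between day 47 and day 26 from 52.3% to 47.1% and 46.8%. Counts of at least 2-fold moved by over 1.5 times in other cases too: day 61 against day 26 gave 9118 with slide as a fixed block, day 61 against day 47 gave 8491 within the shared slide, and midday against midnight gave 16797 with every sequence on its own. The other alternatives run left the total counts of calls within 1.5 times. The gene list tests and their alternative were not run, because no probe is paired with a gene. Signal over background limits the dim targets: of the 68973 tested, 42998 were well above background in all samples.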

Other observations

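Probe families, named in the files by the start of the probe ID, differed in how often they moved. Of 1387 targets read through probes whose names begin with eAryKoshi, 10.4% differed at least 2-fold between midday and midnight, against a median of 16.4% in 10000 random sets matched on signal, and 39.1% had a rhythm of at least 2-fold, against 43.6%. Of 3720 targets with names beginning with maskBest, 13.3% were at least 2-fold lower on day 61 than on day 26, against a median of 10.8%, and 11% were at least 2-fold higher, against 14.3%. In each of these 4 cases the observed share lay at percentile 0 or 100 of the random sets, to 1 decimal. They were picked after the values were seen, from 36 tests of a family and a pattern, of which 9 lay at percentile 0 or 100. The others were maskBest, with 39.6% against 42.8% for the rhythm and 13.9% against 16.2% for midday and midnight, the larger family beginning with 44kb3, with 12.4% against 11.4% higher and 9.06% against 9.84% lower on day 61, and eAry1, with 11.1% against 10.4% lower on day 61. What these families hold is not stated in the sources used here.

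Clock time accounted for 46.3% of the variance over all targets after day, which accounted for 28.1%, and dye for 1.98% after both. These shares are not corrected for the number of levels, 12 clock times against 3 days, and more levels take up more variance by chance. Slide and array were not part of this split.

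Opposed transcripts of both strands were tested as a hypothesis on 1094 pairs of probes that overlap on opposite strands, written before the result was seen. Their median correlation over the 39 samples was 0.043, not below the range of -0.016 to 0.044 that holds the central part of 1000 random re-pairings. Opposition was thus not the rule for such pairs. Single pairs may still be opposed: 144 of the 1094 pairs (13.2%) had a correlation below -0.5, against 10.1% of random pairs, and 194 had one above 0.5, against 12.7% of random pairs.

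The size of the change between consecutive samples was tested against time of day, also written beforehand. The mean SD over targets was 0.543 from 08:00 to 10:00 and 0.372 from 02:00 to 04:00 over the 3 days, and a permutation test over the intervals gave p = 0.25 (100000 permutations within days). Samples that shared an array differed less, by a mean SD of 0.4, than samples on different slides, by 0.525. After removing the means of same-array, same-slide and different-slide pairs the permutation p was 0.068, so a dependence on time of day is neither shown nor excluded.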
